A study of Zea mays with 12 samples.

How the data were processed

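Total RNA of maize leaf 4 was labelled with biotin from 1 µg and hybridised to Affymetrix arrays, 1 per sample, and each sample was pooled from 10 plants, per the labels' protocols. The deposited values are expression values on the log2 scale, 1 table for all 12 arrays, with 2 decimals and a lowest value of 2.12; the submitters' processing notes name affy, GCRMA and limma, with no version. That the values are log2 was read from the values, whose upper quartiles lay between 8.28 and 8.38 on all arrays; the role of each tool is not given in the sources used here. GCRMA estimates background from probe sequence and sets many dim probe sets to nearly one value, so that falls of dim genes cannot be seen, and folds against dim values are lower bounds. Signal over background limits what these arrays show in place of sequencing depth. Between 26.2% and 28.1% of an array's values were at the lowest value. A treatment text in the labels describes fungal sporidia in culture; it contradicts the series design and the sample titles, and the groups follow the titles. The labels do not say that the replicate number is the experiment, so that p-values measure the spread between these samples.

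The table held 17734 probe sets. The 113 Affymetrix controls were left out of the tests and used for array quality. Of 17621 maize probe sets, the 10429 that reached 4 on at least 3 of the 12 arrays were tested. Groups were fitted in limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on the 4 group means, which left 8 residual degrees of freedom. A call required a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1; adjusted p-values of single genes are limma's. The contrasts were infected minus mock at 36 hpi, the same at 96 hpi, the difference of both, and mock 96 minus mock 36 hpi. These settings, the alternatives other than those said to be added, the gene lists and the rule for naming genes were fixed before the data were examined.

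The annotation given names 1 gene for 1452 probe sets and several for 1, and 16168 maize probe sets are unnamed here, so that 8.24% of them carry a name. Of 1108 genes, 1060 were found in the reference table of assembly Zm-B73-REFERENCE-NAM-5.0, and 973 had a readable name. No coordinates are given, since the array names no build. Named genes were the 8 largest rises and 8 largest falls at each time among called probe sets with 1 readable gene whose infected and mock arrays did not overlap, each gene once. Up to 4 called members of each list and the 4 largest in each direction for the other contrasts were also named; list members without a call are given as values. Gene lists were matched on symbols and synonyms, because the annotation holds no descriptions to match. Of 32 lists, 23 with at least 3 measured genes were tested, 6 had fewer and 3 held no gene; 204 genes belonged to a list and 15 to over 1. Before the values of any member were seen, 9 memberships that matched by a shared synonym of another gene were taken out. Lists were tested with camera (preset correlation 0.01) on 1 probe set per gene, with 786 genes as background and adjustment over 69 tests of 3 contrasts; the mock contrast was adjusted on its own. No call of the infection family held with an estimated correlation.

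Array quality was compared by exact two-sided permutation tests. To check whether replicate numbers pair the arrays, deviations from group means were correlated. At 36 hpi same-numbered infected and mock arrays had correlations from 0.302 to 0.631 and other numbers from −0.499 to −0.062. The numbers were therefore taken to pair the 36 hpi arrays; across the times they did not, and at 96 hpi not every correlation was over 0.1.

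Before use, the procedure was tested on simulated data for 10429 genes. In a simulated 36 hpi comparison it recovered 90% of rises of 2, 97.5% of rises of 4 and 80% of falls of 2 on the log2 scale, with 8 false calls among 10229 unchanged genes. In a simulated 96 hpi comparison it recovered 90% of rises of 2 and 95% of rises of 4, with 4 false calls. The changes were put only on probe sets of middle mock level, with independent noise and no pairing. The simulated 36 hpi comparison had 183 calls, where the real one had 10, and more calls ease the adjusted threshold. The rates therefore do not give the power for dim genes or for the real 36 hpi comparison. A shift of 1.5 put on the jasmonate list ranked that list 1 of 23. Alternatives were no filter, a stricter filter at 6, other scalings, values below 4 set to 4, array weights, a trend, replicate blocks, the arrays of 1 time alone, other thresholds, 1 probe set per gene, and each array left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.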

Results

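RNA from leaf 4 of the maize cultivar Nathan was hybridised to 12 single-colour Affymetrix arrays. Leaves had been sprayed with conidia of Colletotrichum graminicola strain CgM2, the fungus of maize anthracnose, or were uninfected controls (mock), and were sampled 36 or 96 hours post infection (hpi). The submitters assign the earlier time to the first, biotrophic stage of the infection, in which the fungus lives in living host cells, and the later one to necrotrophic growth. Each of the 4 groups held 3 arrays, and each array a pool of 10 plants. The design text speaks of 3 independent experiments. Array medians lay between 5.37 and 5.56 on the log2 scale, and between 42.6% and 43.7% of the values of an array were below 4. The mean correlation of an array with the others of its group lay between 0.985 and 0.994. With 3 arrays per group, the number of arrays limits the precision of each value. No array quality measure differed between infected and mock arrays of a time at a Benjamini-Hochberg adjusted p under 0.05. However, 3 against 3 arrays cannot go below an exact permutation p of 0.1. At 96 hpi the array medians reached that p, at 5.50 to 5.56 in infected and 5.37 to 5.44 in mock arrays. So did the shares below 4, at 42.6% to 43.0% against 43.3% to 43.7%. The share below 4 at 36 hpi and the mean correlation with the group at both times also reached it. Between the times, the hybridisation spike controls averaged 9.21 on the 96 hpi arrays and 10.06 on the 36 hpi arrays (exact two-sided permutation p = 0.0022, adjusted 0.044). The 3′ minus 5′ difference of the ubiquitin control was 0.743 against 1.39 (adjusted exact p = 0.044) and that of cyclophilin −0.467 against −0.158 (adjusted exact p = 0.044).

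The first comparison asked how leaves with the fungus in its biotrophic stage differed from mock leaves at 36 hpi. The terpene synthase gene tps6, whose product makes sesquiterpene precursors of maize phytoalexins, rose from 2.12 (SD 0, n = 3) in mock leaves, the lowest value of the table, to 6.82 ± 1.72 (SD, n = 3) in infected leaves. This was a log2 fold change of 4.70 (SE 0.62, adjusted p = 0.0234). The SE pools the spread of the 4 groups, and for tps6 the mock arrays of both times had an SD of 0. It thus understates the spread of the infected arrays of 36 hpi. Over the tested probe sets the median SD was 0.271 in infected and 0.232 in mock arrays of 36 hpi. At 96 hpi it was 0.233 and 0.18, so that a shared spread can understate that of 36 hpi. The chitinase gene chn1 rose 8.38-fold, from 8.61 ± 0.22 to 11.68 ± 0.73 (log2 fold change 3.07, SE 0.31, adjusted p = 0.0084). GT1 was 7.93-fold lower, at 4.93 ± 0.29 against 7.92 ± 0.82 (log2 fold change −2.99, SE 0.44, adjusted p = 0.0394). Where all arrays of the dimmer group were below 4, the fold is given against a level of 4 as a lower bound, which for tps6 was at least 7.06-fold. Its infected arrays stood at 5.77, 8.80 and 5.89, and without infected replicate 2 of 36 hpi the log2 fold change was 3.71 and the bound at least 3.56-fold, with the call kept. Log2 fold changes against values below 4 are the fitted ones and no exact sizes; with values below 4 set to 4, that of tps6 was 2.82 and its call ended (adjusted p = 0.298), and 4 probe sets were called. These were the 3 named genes among 10 called probe sets, 6 higher and 4 lower, of 10429 tested (limma). At an unadjusted p under 0.05 there were 468 probe sets, or 4.49% of those tested. The infected and mock values did not overlap for 826 probe sets (7.92%, against 10% by chance for arrays that can be exchanged, which paired arrays are not). The numbers of the arrays were taken to pair them at this time, from correlations of deviations and not from the labels. Deviations within a group cancel out, so these correlations are not independent of each other. The fit above holds no term for the number. With the number as a block common to both times 16 probe sets were called, 11 higher and 5 lower, of which 9 were among the 10. With a block within each time, which matches that pairing, 16 were called, 13 higher and 3 lower, of which 7 were among the 10. All 3 genes lost their call when the 6 arrays of 36 hpi were fitted alone, with adjusted p of 0.438 for tps6, 0.25 for chn1 and 0.381 for GT1, and with no filter on low values (0.238, 0.0941 and 0.267). Without 1 array, the count of called probe sets ran from 2 (without mock replicate 1 or 3 of 36 hpi or mock replicate 1 of 96 hpi) to 36 (without infected replicate 1 of 36 hpi). In these fits chn1 kept its call each time. The call of tps6 ended in 7 of the 12 such fits (up to adjusted p = 0.127, without mock replicate 1 of 36 hpi) and that of GT1 in 9 (up to 0.214, without infected replicate 2 of 36 hpi).

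Among the gene lists, 4 pathogenesis-related genes were measured at 36 hpi, of which 1 (chn1) rose and 3 were not called. The uncalled members had log2 fold changes of 2.72 (PR-1), 1.13 (pr5, a thaumatin-like protein) and 0.15 (wip1, a wound-induced protease inhibitor, below 4 on all arrays of this time). For PR-1 the mock arrays were below 4, and the value was 1.71 without infected replicate 2 of 36 hpi and 1.56 with values below 4 set to 4. Adjusted over the list alone, 3 members were higher. The list stood above the other genes (camera adjusted p = 2.53e-05), a call lost with an estimated correlation (adjusted p = 0.175 with an estimated correlation). Of 3 measured terpenoid genes, tps6 rose, an2, an ent-copalyl diphosphate synthase gene of kauralexin synthesis, had a log2 fold change of 2.75 and tps1 one of −0.45. The value of an2 rested on infected replicate 2 of 36 hpi, at 8.01 where the other infected arrays were at 3.47 and 3.77 and the mock arrays below 4; it was 1.29 without that array and 1.34 with values below 4 set to 4. Adjusted over the list alone, 2 were higher. The list was called (camera adjusted p = 0.0394), but not with an estimated correlation (adjusted p = 0.258 with an estimated correlation) or with the number as a block (adjusted p = 0.0782). Nor was it called with a block within each time (adjusted p = 0.258) or with values below 4 set to 4 (0.231). It was also lost without any of 6 arrays, infected replicate 1 and mock replicates 2 and 3 of 36 hpi and infected replicate 1 and mock replicates 1 and 3 of 96 hpi (adjusted p from 0.0522 to 0.105). Of 11 measured genes of glycolysis, fermentation and the TCA cycle none was called over all probe sets, and 2 were higher adjusted over the list alone. The largest values were 2.32 for gpc4 and 1.19 for gpc3, genes of cytosolic glyceraldehyde-3-phosphate dehydrogenase, and 1.15 for the pyruvate decarboxylase gene pdc3, whose mean was below 4 in both groups. For gpc4 infected replicate 2 of 36 hpi stood at 7.26, the other infected arrays at 3.49 and 4.20 and the mock arrays below 4, and the value was 1.19 without that array and 1.15 with values below 4 set to 4. This list passed at a camera adjusted p of 0.0484, but not with an estimated correlation (adjusted p = 0.419 with an estimated correlation) or with the number as a block (adjusted p = 0.0504). Nor did it pass with a block within each time (adjusted p = 0.145) or with values below 4 set to 4 (0.207). It was also lost without infected replicate 1 or 2 or mock replicate 1 or 3 of 36 hpi, or infected replicate 1 or mock replicate 3 of 96 hpi (adjusted p from 0.0643 to 0.3). All other tested lists had adjusted p between 0.184 and 0.983 and no called member, although adjusted over the list alone the ACC oxidase gene ACO31 was higher (1.45, or 0.83 without mock replicate 1 of 36 hpi) and the vacuolar invertase gene ivr2 was lower (−1.02). The glutathione S-transferase gene gst30 had an uncalled log2 fold change of 4.07 (limma adjusted p = 0.647). Its infected arrays stood at 3.46, 8.35 and 8.69 and its mock arrays below 4, and the value was 3.01 with values below 4 set to 4. Its effect at 96 hpi was larger by 2.36, which was not called (limma adjusted p = 0.642).

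**Figure D1:**
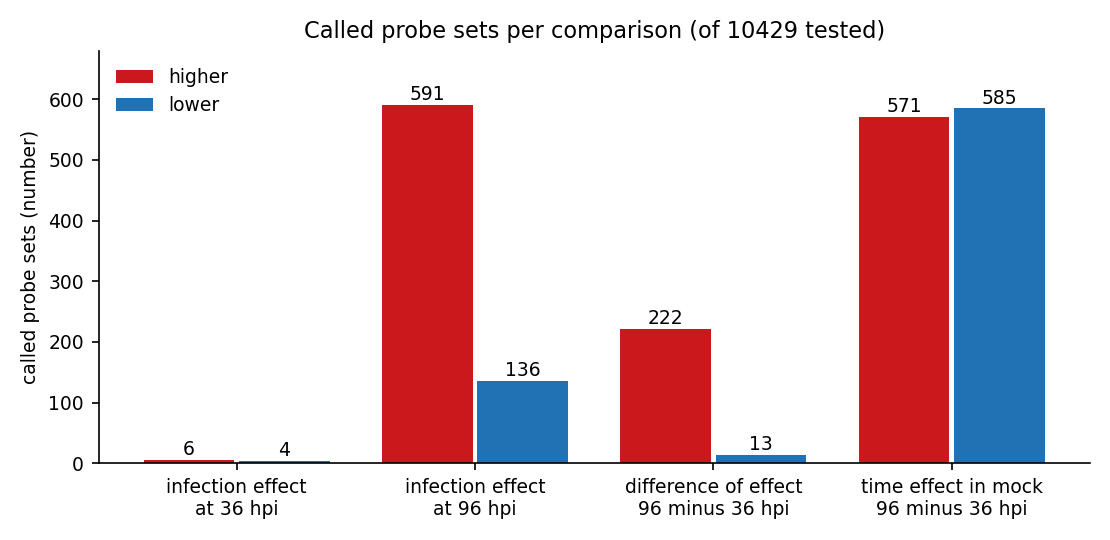
Number of probe sets called higher (red bars) and lower (blue bars) in each comparison, by limma on 12 arrays, 3 per group. The bars stand at 6 and 4 for infection at 36 hpi and at 591 and 136 for infection at 96 hpi.

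The second comparison asked the same of the necrotrophic stage at 96 hpi. The terpene synthase gene tps6 reached 12.71 ± 0.37 (SD, n = 3) against 2.12 in mock leaves, which is at least 419-fold (adjusted p = 1.18e-06). PR-1 rose 558-fold, to 13.12 ± 0.37 from 4.00 ± 0.64 (log2 fold change 9.12, SE 0.70, adjusted p = 8.99e-06). Its mock replicate 1 of 96 hpi was at 3.35, and with values below 4 set to 4 the log2 fold change was 8.91. The kauralexin gene an2 rose at least 156-fold (adjusted p = 9.7e-05) and wip1 at least 82.1-fold (adjusted p = 1.57e-08). The other genes among the 8 largest rises of named genes were sip1 (at least 69.6-fold), gpc4 (at least 57.4-fold), the glutathione S-transferase gene gst30 (86.2-fold, adjusted p = 0.00638) and the alternative oxidase gene aox3 (at least 22-fold, adjusted p = 2.06e-05). The fold of gst30 was 48.1 without mock replicate 1 and 178 without mock replicate 3 of 96 hpi, and its adjusted p reached 0.0362 with no filter on low values. All 8 kept their call in each of 23 alternative settings.

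The 8 largest falls among named genes were smaller. The polyamine oxidase gene mpao1 had a log2 fold change of −2.71 (SE 0.75, adjusted p = 0.041), at 6.87 ± 1.39 against 9.58 ± 0.89. The cytokinin oxidase gene cko3 was at −2.57 (SE 0.64, adjusted p = 0.0257), and its other probe set at −1.28. Without infected replicate 1 of 96 hpi cko3 was at −3.44 and mpao1 at −3.30, and without infected replicate 2 mpao1 was at −1.95. The phosphoethanolamine methyltransferase gene PEAMT was at −1.68, GT1 at −1.62, the starch branching enzyme gene sbe1 at −1.56 and the benzoxazinoid gene bx6 at −1.34. Hcf106C, of thylakoid protein transport, was at −1.17, and sig3, a plastid sigma factor gene, at −1.16. Each of these 8 calls ended without infected replicate 2 of 96 hpi, among other arrays. The adjusted p without that array was 0.161 for mpao1, 0.116 for cko3, 0.159 for GT1, 0.115 for sbe1, 0.064 for Hcf106C and 0.112 for sig3. PEAMT and bx6 reached 0.066 and 0.0665 without mock replicate 2 of 96 hpi. With no filter on low values all of the 8 but Hcf106C lost their call (adjusted p from 0.0504 to 0.121), as did all but sig3 with the 6 arrays of 96 hpi alone (0.0593 to 0.0896).

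In all, 727 of 10429 probe sets were called at 96 hpi (limma), 591 higher and 136 lower. With every array centred on its median there were 840 calls, 543 higher and 297 lower, so that the share of higher calls was 64.6% in place of 81.3%. That centring moved the median of all tested probe sets by −0.117, from −0.11, and relative to it 543 probe sets were higher. The count was 481 (439 higher and 42 lower) without infected replicate 2 of 96 hpi and 1143 (724 and 419) without infected replicate 1. The lower calls were 89 without infected replicate 3 and 79 and 64 without mock replicates 1 and 2 of 96 hpi. With the adjusted p alone 754 were higher and 470 lower (61.6% higher), and with array weights 759 and 453 (62.6%). The groups did not overlap for 3813 probe sets (36.6%, against 10% by chance). The calls covered 89 named genes, 77 higher and 12 lower.

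**Figure D2:**
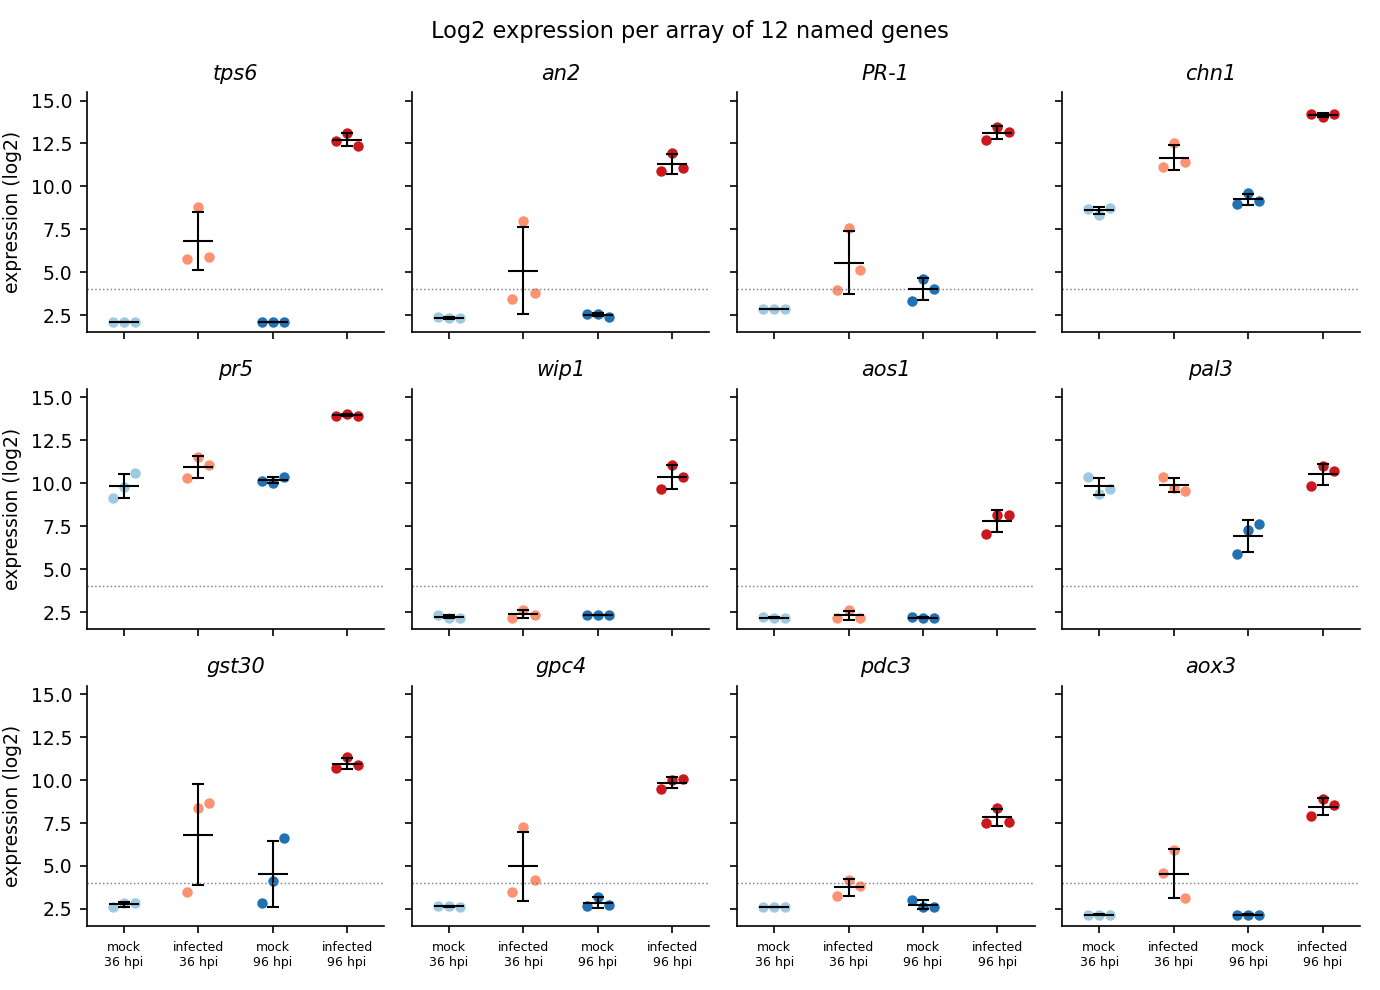
Log2 expression of 12 genes on each of the 12 arrays (dots), with group means and SD (black, n = 3); the dotted line marks 4. Infected leaves at 96 hpi lay above mock leaves in all 12 panels, with tps6 at a mean of 12.71 against 2.12.

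All 4 measured pathogenesis-related genes rose at 96 hpi: PR-1, wip1, chn1 (29.9-fold, to 14.16 ± 0.09) and pr5 (13.7-fold). All 4 were also higher adjusted over the list alone, and the median log2 fold change was 6.46, or 5.63 with values below 4 set to 4 (camera adjusted p = 8.23e-07; adjusted p = 0.175 with an estimated correlation). Of 18 measured glutathione S-transferases, which conjugate glutathione to toxic compounds, 6 rose and 12 were not called, and the same numbers held adjusted over the list alone. Besides gst30, gst8 rose at least 18.8-fold, gst23 rose 5.62-fold and gst7 had a log2 fold change of 2.67, whose call ended without infected replicate 2 of 96 hpi (adjusted p = 0.0798) and whose fold was 3.27 without mock replicate 1 and 10.1 without mock replicate 3 of 96 hpi. The median of the list was 0.957 (camera adjusted p = 0.00274; adjusted p = 0.522 with an estimated correlation). Of 11 measured genes of glycolysis, fermentation and the TCA cycle, 5 rose and 6 were not called, with the same numbers adjusted over the list alone. These 5 were gpc4, gpc3 (15.8-fold), the pyruvate decarboxylase genes pdc3 (at least 14.3-fold) and pdc2 (8.38-fold), and the alcohol dehydrogenase gene adh1 (log2 fold change 1.76). None of them belongs to the TCA cycle. The enolase genes eno1 (−0.07) and eno2 (0.47) were not called. The list median was 0.91 (camera adjusted p = 0.00105; adjusted p = 0.175 with an estimated correlation).

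Of 8 measured genes of sucrose and starch synthesis, sbe1 fell and 7 were not called, also when adjusted over the list alone. All 8 had values below 0, with a median of −0.48 (camera adjusted p = 0.0329; adjusted p = 0.4 with an estimated correlation), and the call was lost without mock replicate 1 (adjusted p = 0.0522) or 3 (0.0643) of 96 hpi, or with values below 4 set to 4 (0.0774). Of 3 measured protease inhibitor genes, 1 (wip1, also a member of the pathogenesis-related list) rose over all probe sets and over the list alone. The cystatin gene cpi2 (0.34) and psei1 (0.41) were not called. The median was 0.407 and the mean 2.92 (camera adjusted p = 0.0326; adjusted p = 0.343 with an estimated correlation), and without mock replicate 2 of 96 hpi the adjusted p was 0.0503.

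Other lists held called members without passing the list test. Of 3 measured terpenoid genes, tps6 and an2 rose and tps1 was not called (camera adjusted p = 0.0873), and the self-contained test fry gave an adjusted p of 4.49e-05. Of 7 measured jasmonate genes, only aos1, for allene oxide synthase, rose (at least 13.8-fold, adjusted p = 1.58e-07), also in each of the 3 other scalings tried. The list median was 0.35 (camera adjusted p = 0.229). Of 6 measured chaperones, the binding protein genes bip2 (5.95-fold) and bip1 (log2 fold change 1.82) and the calreticulin gene crt2 (1.81) rose. For bip2, infected leaves stood at 9.73 and mock leaves at 7.15 at 96 hpi, against 8.62 in mock leaves at 36 hpi. The call of crt2 ended without infected replicate 2 of 96 hpi (adjusted p = 0.0877), and the list had a camera adjusted p of 0.0674. Of 4 measured benzoxazinoid genes, bx6 fell and 3 were not called (median −1.16, camera adjusted p = 0.323). With the arrays centred on their medians 2 fell, and adjusted over the list alone 3 were lower and glu1 (1.65) was higher. The sucrose synthase gene sh1 rose 5.06-fold among 5 measured genes of sucrose cleavage and transport (camera adjusted p = 0.364). ACO31 rose 5.21-fold among 3 ethylene genes (adjusted p = 0.288). The glutamine synthetase gene GLN6 was 4.86-fold higher than in mock leaves among 8 genes of nitrogen assimilation (adjusted p = 0.983). It stood at 10.21 in infected and 7.93 in mock leaves at 96 hpi, against 9.92 in mock leaves at 36 hpi. The tryptophan synthase gene orp2 (1.65) rose among 4 shikimate pathway genes (median 0.287, mean 0.13, camera direction down, adjusted p = 0.983), and its call ended without infected replicate 2 of 96 hpi (0.168). The protease gene mir2 (1.29) rose among 8 genes of senescence and protein breakdown (adjusted p = 0.855), a call lost with array weights (0.90) and with the 6 arrays of 96 hpi alone (adjusted p = 0.0633). Those 6 arrays alone also ended the calls of gst7 (0.087) and orp2 (0.0611), and no filter on low values those of gst7 (0.0687), crt2 (0.0726) and orp2 (0.116).

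Of the lists with 2 measured genes, which were not tested as lists, the phenylpropanoid list held pal3, for phenylalanine ammonia-lyase, which rose 12.1-fold. It stood at 10.52 ± 0.61 in infected and 6.93 ± 0.94 in mock leaves at 96 hpi, against 9.81 ± 0.50 in mock leaves at 36 hpi. The flavanone hydroxylase gene f3h of the flavonoid list rose 8.50-fold (4.91-fold without infected replicate 2 and 15.1-fold without infected replicate 1 of 96 hpi), a call lost with the 6 arrays of 96 hpi alone (adjusted p = 0.055). The cell cycle gene cdc2 was at 1.06, a call lost with 2 other scalings and without infected replicate 2 of 96 hpi (adjusted p = 0.183). The chlorophyll synthesis genes elm1 (−0.90) and oy1 (−0.82) and the ribosomal genes RPL10 (0.55) and rps6 (0.36) were not called.

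No member was called among 9 genes of the photosynthetic light reactions (median −0.123, camera adjusted p = 0.635), 8 of the Calvin cycle and C4 photosynthesis (median −0.092, adjusted p = 0.635), 8 reactive oxygen enzymes (adjusted p = 0.983) or 11 wall genes (adjusted p = 0.958), although in the wall list 1 gene was lower with the arrays centred on their medians. Of the lists that mark leaf cell types, mesophyll genes (3, median −0.03, adjusted p = 0.855), bundle sheath genes (3, median −0.09, adjusted p = 0.916) and vascular genes (3, adjusted p = 0.855) held no called member. Among 4 epidermis and cuticle genes 1, the lipid transfer gene plt2, was higher (2.06), a call lost without infected replicate 2 of 96 hpi (adjusted p = 0.145) and at 1.47 without mock replicate 1 (0.132), with a list p of 0.765. For plt2, infected leaves stood at 12.02 and mock leaves at 9.96 at 96 hpi, against 11.62 in mock leaves at 36 hpi. The 8 reference genes had a median of 0.28 and no call (adjusted p = 0.364). Over the 3 infection contrasts, 13 of 69 list tests were called, of which 0 held with an estimated correlation, while 17 were called by fry. Of these 17, 10 were among the 13. Not called by fry were glycolysis, fermentation and the TCA cycle at 36 hpi (fry adjusted p = 0.087) and, for the difference between times, sucrose and starch synthesis (0.07) and the glutathione S-transferases (0.0723).

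**Figure D3:**
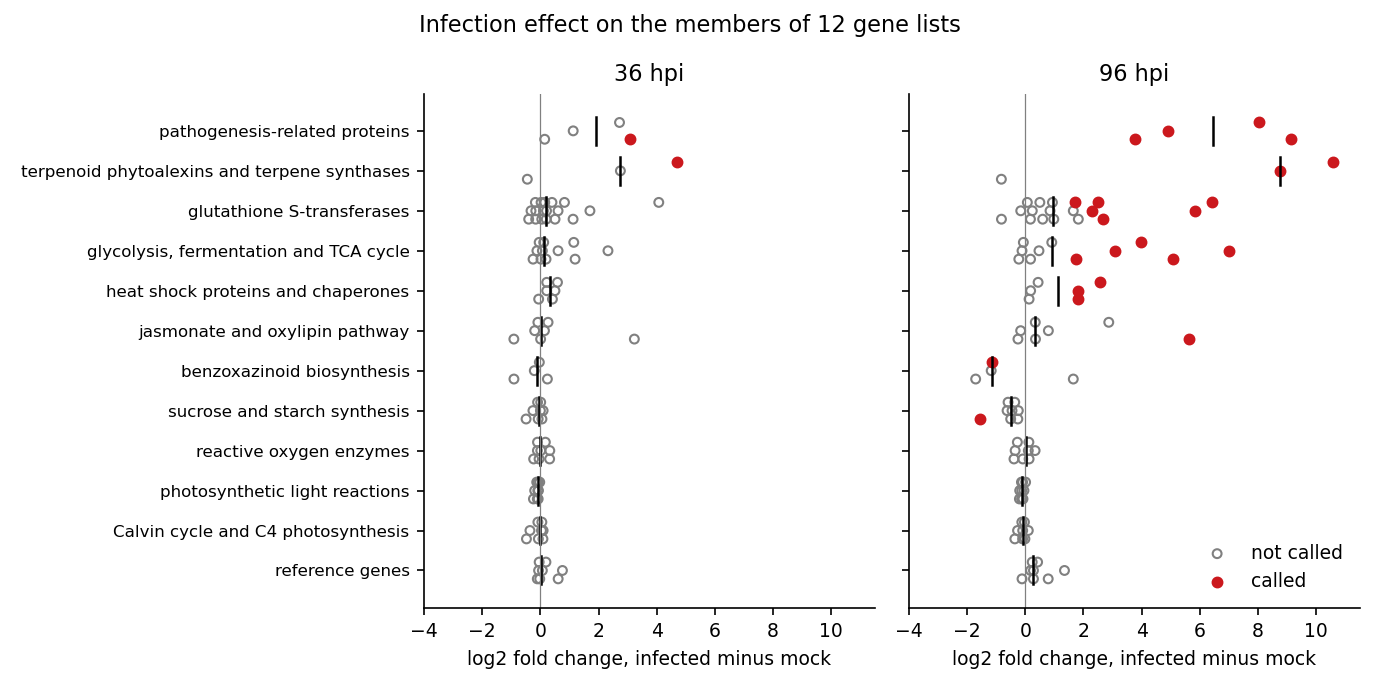
Log2 fold change (infected minus mock) of each measured member of 12 gene lists at 36 hpi (left) and 96 hpi (right); filled dots are called members, open dots are not, and black lines are list medians. The 4 pathogenesis-related genes are filled at 96 hpi and 1 of them at 36 hpi.

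The third comparison tested whether the infection effect differed between the times. The effect on wip1 was larger at 96 hpi by 7.88 on the log2 scale (SE 0.39, adjusted p = 8.03e-07), that on sip1 by 6.55 (SE 0.37, adjusted p = 2.67e-06), that on PR-1 by 6.40 (SE 0.98, adjusted p = 0.00512) and that on an2 by 6.01 (SE 1.29, adjusted p = 0.0369). All 4 rest on groups below 4, wip1 on 3 of its 4 groups, so that these sizes are not exact; with values below 4 set to 4 they were 6.36, 6.08, 7.35 and 5.95, all called. Infected replicate 2 of 36 hpi bore on both PR-1 and an2, whose differences were 7.41 and 7.47 without it. Without infected replicate 1 of 36 hpi they were 5.62 and 5.20, and without infected replicate 3 an2 was at 5.35. The difference for an2 was not called in 10 of the 12 fits without 1 array (adjusted p = 0.107 without infected replicate 2 of 96 hpi). For AGP2 the effect was lower at 96 hpi by −1.20 (adjusted p = 0.0402). That call was lost with the number as a block (0.0689), with no filter (0.0852) and in 9 of the 12 fits without 1 array (up to 0.117, without mock replicate 2 of 96 hpi). There were 235 called probe sets (limma), 222 higher and 13 lower. Without infected replicate 1 of 96 hpi there were 448, 339 higher and 109 lower, and with array weights 506, 389 higher and 117 lower. The pathogenesis-related genes differed as a list (3 of 4 higher, and 4 adjusted over the list alone; camera adjusted p = 8.23e-07; adjusted p = 0.175 with an estimated correlation). The protease inhibitors passed the same test (0.00124; adjusted p = 0.175 with an estimated correlation), but of their 3 genes only wip1, also in the list before, was higher, with a list median of 0.68 against a mean of 3.03. Of the 11 glycolysis and fermentation genes 5 were higher, or 4 with quantile normalization or centring on medians (camera adjusted p = 0.00124; adjusted p = 0.175 with an estimated correlation). Of the 18 glutathione S-transferases 2 were higher (0.0144; adjusted p = 0.564 with an estimated correlation). Sucrose and starch synthesis had 0 of 8 called members and stood lower (0.0484; adjusted p = 0.437 with an estimated correlation). That call was also lost with quantile normalization (0.0553), with values below 4 set to 4 (0.12) and without any of 8 arrays, all but mock replicate 1 of 36 hpi, infected replicates 1 and 3 of 96 hpi and mock replicate 2 of 96 hpi (0.0527 to 0.103).

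Of the 10 probe sets called at 36 hpi, 8 were called in the same direction at 96 hpi, 6 higher and 2 lower, tps6, chn1 and GT1 among them. The count was 3 with values below 4 set to 4 and 0 with no filter. Without 1 array it ran from 1 (without mock replicate 1 or 3 of 36 hpi or mock replicate 1 of 96 hpi) to 29 (without infected replicate 1 of 36 hpi). It was 2 to 5 without the others, except 9 without infected replicate 1 of 96 hpi. Lists of these sizes that are independent would share 0.34 and 0.052 (one-sided Fisher's exact p = 3.23e-08 and 0.000996, across probe sets, which are not independent). The comparisons share no arrays but share the estimate of the spread. The 6 arrays of 36 hpi alone gave 0 calls, so that the calls at 36 hpi rest on this shared estimate. The lists are thus not independent, and the Fisher p cannot decide on a shared response. Of the 591 probe sets higher at 96 hpi, 516 (87.3%) had a fold change above 0 at 36 hpi, against 48.7% of all tested. Their medians were 2.18 at 96 hpi and 0.38 at 36 hpi. Of the 136 lower ones, 111 (81.6%) were below 0 at 36 hpi, against 51% of all tested.

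**Figure D4:**
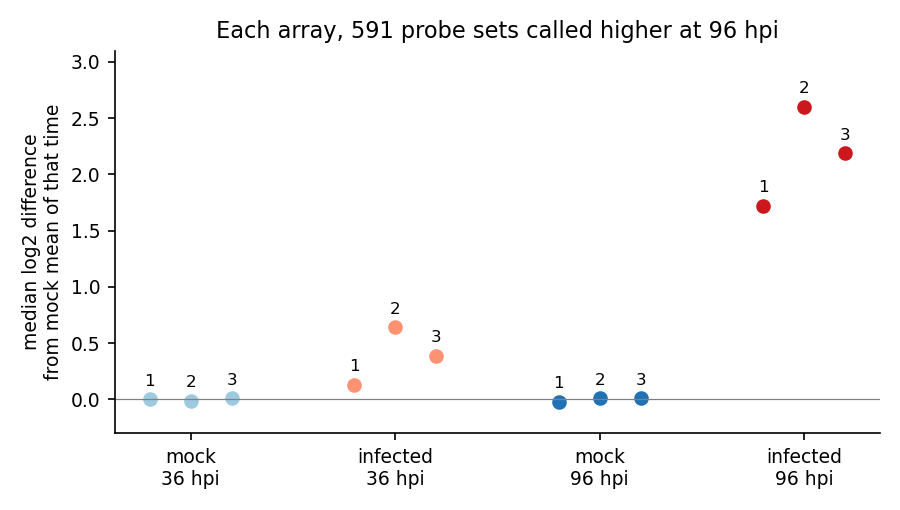
Median over 591 probe sets called higher at 96 hpi of the log2 difference between each array (dots, with replicate number) and the mock mean of its time. Infected arrays lie at 0.13, 0.64 and 0.39 at 36 hpi and between 1.72 and 2.60 at 96 hpi; these probe sets were chosen on the 96 hpi arrays.

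As background, mock leaves were compared between the times. The vacuolar invertase gene ivr2 was at least 19.8-fold lower at 96 than at 36 hpi, at 2.28 ± 0.03 against 8.31 ± 0.68 (log2 fold change −6.03, SE 0.30, adjusted p = 6.37e-06). Of 11 measured wall genes 8 fell, 7 of them cellulose synthase genes, with cesa7 9.36-fold, cesa2 9.30-fold and CesA-9 6.25-fold lower; with other scalings between 6 and 9 fell. The expansin gene expa1 was at −3.30, a call lost without mock replicate 1 of 36 hpi (−2.61, adjusted p = 0.136) or mock replicate 3 (−3.89, 0.0557), with quantile normalization (0.0597), with centring on medians (0.051) or with values below 4 set to 4 (0.0684). The list, in which 8 members were also lower adjusted over the list alone, had a median of −1.54, or −1.15 with values below 4 set to 4 (camera adjusted p = 8.23e-05; adjusted p = 0.535 with an estimated correlation). The aquaporin genes nip2b (11.1-fold) and PIP1-5 (6.62-fold), the malate synthase gene mas1 (at least 4.47-fold) and pdlk2, for a pyruvate dehydrogenase kinase (6.88-fold), rose. Of 8 senescence genes, 4 rose, and between 3 and 5 with other scalings (lls1 1.57, see2b 1.14 and the mir3 loci 1.33 and 1.00; camera adjusted p = 0.00747; adjusted p = 0.535 with an estimated correlation). A fit with a block within each time compares the fitted levels of replicate 1 at each time and not the group means. In that fit see2b (adjusted p = 0.0613) and the mir3 loci (log2 fold changes 0.97 and 0.69) were not called, which is no test of pairing. The glutamine synthetase gene GLN6 (−1.98), pal3 (−2.88) and the tubulin gene tua5 of the reference list (−2.23, or −1.59 without mock replicate 1 of 96 hpi) fell. In total 1156 probe sets were called (limma), 571 higher and 585 lower. There were 690 higher and 478 lower with the arrays centred on their medians, and 504 and 673 when centred on the tested probe sets. With a block within each time, and so for the levels of replicate 1, there were 1161 calls, of which 689 were among the 1156. These are calls of another contrast. RNA and array controls moved with the time in mock leaves, from 36 to 96 hpi: the spike controls from 10.15 to 9.27, the 3′ minus 5′ difference of ubiquitin from 1.30 to 0.837 and that of cyclophilin from −0.223 to −0.517, and 18S ribosomal RNA from 2.85 to 3.54 (exact two-sided permutation p = 0.1 each, the smallest that 3 against 3 arrays allow).

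**Figure D5:**
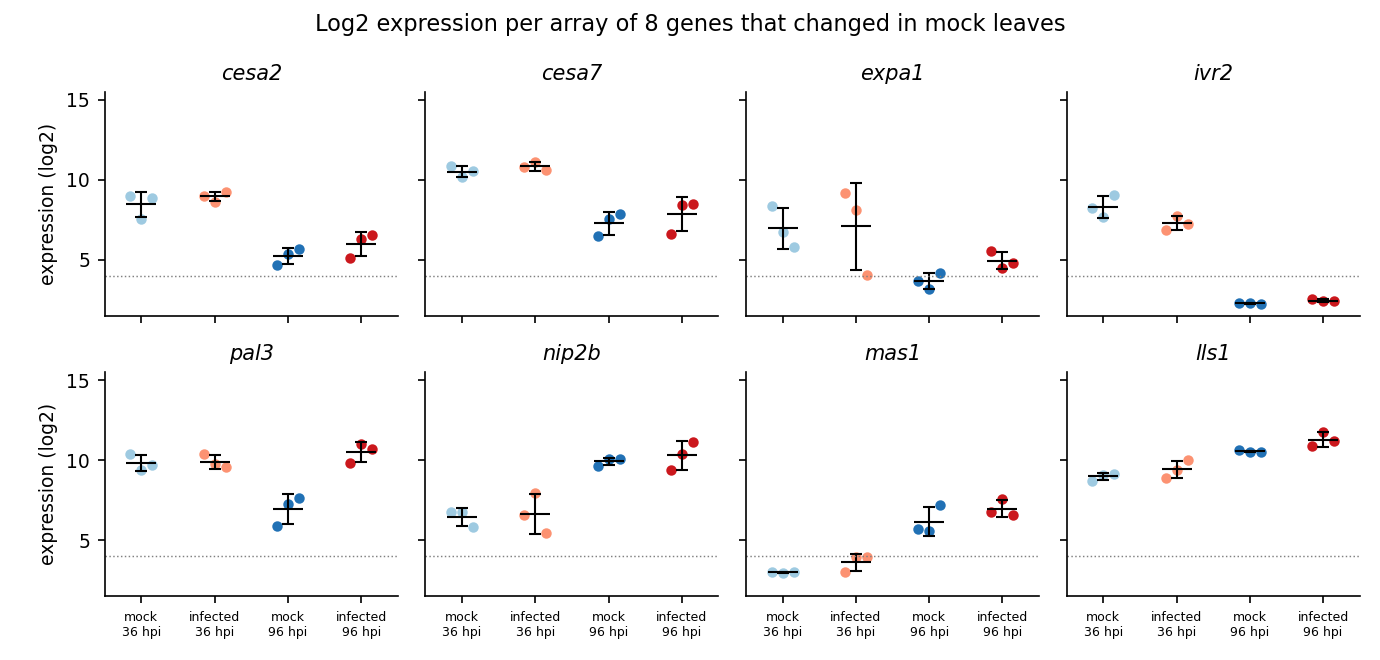
Log2 expression on each array (dots) of 8 genes that differed between mock leaves of 36 and 96 hpi, with group means and SD (black, n = 3); the dotted line marks 4. Mock leaves at 96 hpi lay below those at 36 hpi for the 5 genes from cesa2 to pal3 and above them for nip2b, mas1 and lls1.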

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

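Of the tests in this part, those of other splits of the arrays, of array scaling (as a test of this pattern, on settings that were planned except centring on the tested probe sets), of values below 4 set to 4 and of the spike controls as a mark of handling were chosen after the results were seen; those of bright probe sets, fungal RNA, hybridisation efficiency, swapped labels and a whole array set higher were written down before their results. The results here stand out because the infection effect differed between 36 and 96 hpi by a test of the difference itself (limma). For 235 probe sets that difference was called. In log2 units, 96 minus 36 hpi, it was 7.88 for wip1, 6.55 for sip1, 6.40 for PR-1, 6.01 for an2, 5.89 for tps6, 5.80 for gst8 and 5.48 for aos1. It was 4.66 for gpc4, 3.94 for pdc3, 3.90 for aox3, 3.51 for pal3, 3.32 for pdc2, 2.79 for gpc3, 2.65 for pr5, 2.65 for sh1 and −1.20 for AGP2. Sizes that rest on groups below 4 are not exact. With values below 4 set to 4, the difference was 6.36 for wip1, 6.08 for sip1, 7.35 for PR-1, 5.95 for an2, 4.23 for gst8, 3.79 for aos1, 4.69 for gpc4, 3.77 for pdc3, 3.61 for aox3 and 2.98 for pdc2, all called. Without infected replicate 2 of 36 hpi it was 7.41 for PR-1, 7.47 for an2, 6.88 for tps6 and 5.80 for gpc4, and the effect on aox3 at 36 hpi was 1.70 in place of 2.40. Without infected replicate 1 of 36 hpi it was 5.62 for PR-1, 5.20 for an2 and 3.92 for gpc4, and without infected replicate 3 it was 5.35 for an2, 3.18 for aox3 and 2.73 for pdc2. Of the 12 fits without 1 array, the call ended in 10 each for gpc4 (adjusted p up to 0.108) and an2, 9 for AGP2, 7 each for aox3 (up to 0.0654) and gpc3 (up to 0.103), and 2 each for pal3 (up to 0.0521) and pr5 (up to 0.0532). The lists that differed were the pathogenesis-related proteins (camera adjusted p = 8.23e-07), the protease inhibitors (0.00124, through wip1, with a median of 0.68), glycolysis, fermentation and TCA cycle (0.00124), the glutathione S-transferases (0.0144) and, lower, sucrose and starch synthesis (0.0484, or 0.12 with values below 4 set to 4); none of the 5 held with an estimated correlation.

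Other splits of the same arrays were counted. With 10 possible splits of 6 arrays no share under 0.05 can be reached. At 36 hpi, 2 of 10 splits gave at least the real 10 calls, and the highest other gave 115. That split put both arrays of number 1 on one side and both of number 3 on the other, which points to a structure of the samples along the numbers; with the number as a block 16 probe sets were called. The other splits that part all 3 pairs gave 0 calls. At 96 hpi 1 of 10 splits gave as many as the real 727, and the highest other gave 30. For mock leaves over time 1 of 10 gave the real 1156, and the highest other gave 0. For the difference between the times, 5 of 100 drawn splits gave at least the real 235 and the highest other gave 615. The 4 splits with more calls exchanged mock arrays alone and so left the change with time uncancelled, which points to that structure of the samples and says nothing about chance. The additive effects of time and infection were also removed from each probe set first. Of the same 100 splits 1, the real one, then gave as many as 235, and the highest other gave 1. This would argue against chance only for arrays that can be exchanged. The correlations by number at 36 hpi and the spike controls go against free exchange, so the count cannot decide.

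The first pattern is that 81.3% of the calls at 96 hpi were higher. Over 4 scalings of the arrays the lowest share was 64.6%, with the adjusted p alone it was 61.6%, and with array weights 62.6%, while leaving out 1 array moved it from 63.3% (without infected replicate 1) to 91.3% (without infected replicate 2 of 96 hpi), so that a shift of whole arrays stays open for part of the excess. Falls that vanish below the floor might add to it, but among 4941 probe sets with a mean of at least 8 the share was 74.5%, which ranged from 50% to 89.6% without 1 array and from 52.6% to 76% over 4 scalings, and leaves this open. Fungal RNA binding to maize probes would raise probe sets that mock leaves lack, and 25% of the higher calls (148 of 591) were below 4 on all mock arrays of 96 hpi, which neither excludes it nor shows it. A response of the plant to the fungus, which the design names, remains an open explanation and cannot be told apart from these here.

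The second pattern is the difference of mock leaves between the times, 1156 probe sets. The spike controls differed by −0.84 between the times (exact permutation p = 0.0022, adjusted 0.044), and with all arrays of a time possibly handled together, handling cannot be told apart from time. As a test of hybridisation efficiency, the change with the spike level within groups gave a median of −9% of the time effect over these probe sets. It lay between −15.8% and 10.9% without 1 array. The spike level had SDs of only 0.16 to 0.33 within groups, and the slope was carried over a larger difference between the times. Noise in such slopes can hide an effect, so the test cannot decide. Ageing of the leaf, which the sampling times imply, stays open and was not tested. The plants were kept at 15 h light and 9 h dark, with 28 °C by day and 20 °C by night. If all leaves were sprayed at the same hour, the sampling times fall at different points of this cycle. Time of day then cannot be told apart from time since infection, here or in the difference of the infection effect between the times.

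The third pattern is the spread of the infected arrays at 36 hpi, whose medians over the 591 probe sets higher at 96 hpi were 0.13, 0.64 and 0.39 above the mock mean. The lowest infected array lay 0.11 above the highest mock array, which goes against swapped labels of an infected and a mock array. The mock arrays are part of the mean they were set against, and the margin has no measured spread, so the test is weak. Over all maize probe sets, infected replicate 1 of 36 hpi correlated more with mock replicate 1 (0.9947) than with the other infected arrays (0.9894 and 0.9882). The medians of all tested probe sets spread by 7.1% of that range, so that no whole array was set higher in the deposited values. Array medians of this group lay between 5.50 and 5.54 after the submitters' processing, so the test could hardly come out otherwise. An effect of the processing that depends on signal level was not tested. Uneven infection of the leaf pools and a label exchanged with a sample from outside stay open and were not tested.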

How the results depend on the processing

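Blocks within each time, centring on the tested probe sets, values below 4 set to 4 and lists with the removed memberships kept were chosen after seeing the data; all other alternatives were planned. Of the values with a test or count, 102 stayed within their limits and 47 moved. Among named genes, 1449 of the values kept direction and call, 224 lost the call and 0 reversed. For lists these were 1823 and 55, with 33 gaining a call and 1 reversed: sucrose cleavage and sugar transport in mock leaves over time (fry adjusted p = 0.0299, down, where camera points up). With no filter on low values, which adds probe sets near the floor, calls fell to 0 at 36 hpi (limma; 628 of 17621 at an unadjusted p under 0.05), 129 for the difference and 0 shared. Values below 4 set to 4, which takes differences below that level away, gave 4 calls at 36 hpi and 3 shared. The 6 arrays of 36 hpi alone gave 0 (limma; 430 at an unadjusted p under 0.05). An adjusted p under 0.01 gave 1 at 36 hpi, 130 for the difference, 720 for mock leaves over time and 1 shared. The adjusted p alone gave 1224 at 96 hpi and 2529 for mock leaves. With 1 probe set per gene, fewer are tested: 3, 85, 35 and 96 calls for 36 hpi, 96 hpi, the difference and mock leaves, and 3 shared. Array weights gave 1212 at 96 hpi and 506 for the difference, with weights from 0.352 to 8.73; the cause was not tested. The number as a replicate block gave 16 calls at 36 hpi, and the block within each time 16 there and 411 for the difference. For mock leaves over time the block within each time compares the fitted levels of replicate 1, so its values there are not those of the group means. At 96 hpi same-numbered arrays had correlations of 0.488, 0.075 and 0.366 and other numbers from −0.469 to 0.224, so that pairing there is unresolved. The number as a block gave 796 calls at 96 hpi, with mpao1 not called (adjusted p = 0.0538), and the block within each time gave 925. With the number as a block, the protease inhibitors at 96 hpi and the sucrose and starch list for the difference were no longer called (camera adjusted p = 0.0504 for each). Besides the lists at 36 hpi given with the results and the chaperones in mock leaves over time, which gained a call, the number as a block changed no other list call. With the block within each time the protease inhibitors had an adjusted p of 0.141 and the sucrose and starch list one of 0.0659. Of the list tests, 0 in place of 13 were called with an estimated correlation. Leaving out each array in turn gave between 2 and 36 calls at 36 hpi (36 without infected replicate 1, 2 without mock replicate 1), 481 and 1143 at 96 hpi, 167 and 448 for the difference, and 1 and 29 shared calls. Signal over background limits falls of dim genes.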

Other observations

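All lists in this part were chosen after the values were seen, so that their camera p-values cannot decide whether a list changed as a set. Beyond the fixed lists, the genes of the anaerobic response of maize, which serve sugar breakdown without oxygen, held 12 measured members at 96 hpi, of which 8 rose: gpc4, gpc3, pdc3, pdc2, adh1, sh1, the aldolase gene ald1 (log2 fold change 1.25) and the hemoglobin gene GLB1 (4.24). The list median was 2.05. At 36 hpi 0 members were called (camera adjusted p = 0.183), and 7 of 12 were called for the difference between times (1.98e-07; adjusted p = 0.101 with an estimated correlation). Of these 12 genes, 9 were also in a fixed list. Of 3 alternative oxidase genes, whose products carry electrons past the cytochrome path in mitochondria, 2 rose at 96 hpi: aox3 and aox1 (3.13; camera adjusted p = 0.00631; adjusted p = 0.101 with an estimated correlation).

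Protein folding genes of the endoplasmic reticulum held 7 higher calls among 16 at 96 hpi, bip1, bip2, crt2, the calnexin gene CNX and the disulfide isomerase genes pdi3, pdi4 and pdi8 (median 0.545, camera adjusted p = 0.00432; adjusted p = 0.489 with an estimated correlation). Of these 16 genes, 3 were also in a fixed list. Of 18 cytokinin genes, HK1 was higher (1.26) and cko3 lower (−1.28; list median −0.49, camera adjusted p = 0.0388; adjusted p = 0.489 with an estimated correlation). Of 19 aquaporin genes 0 were called for infection at 96 hpi, and 5 rose with time in mock leaves (camera adjusted p = 0.0467; adjusted p = 0.489 with an estimated correlation). Of 9 primary wall cellulose synthases, all of them members of the fixed wall list whose falls are given with the mock comparison, 7 fell with time in mock leaves (6.63e-05; adjusted p = 0.253 with an estimated correlation).

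A hypothesis is that genes of the anaerobic response rose together at 96 hpi. The list stood above the other genes (camera adjusted p = 2.31e-06), but not with an estimated correlation (adjusted p = 0.121 with an estimated correlation), and since it was drawn up after gpc4 and pdc3 had been seen, the test cannot decide; oxygen in the leaves was not measured.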
